A study of Mus musculus with 10 samples.

How the data were processed

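The series comprises 10 ChIP-seq samples from mouse mammary tissue on the day of parturition, in wild type mice and in mice without Stat5a. Per the labels' protocols, frozen tissue was powdered and fixed with formaldehyde, nuclei were isolated on a sucrose gradient, chromatin was sonicated, and the immunoprecipitated DNA was sequenced on an Illumina HiSeq instrument. Antibodies against STAT5A, STAT5B, RNA polymerase II and H3K4me3 were used. Peak lists of 3 samples were analysed, each of 1 library as far as the labels say. The other 7 samples were not used here. Groups were taken from the sample titles, and the series' design text gives the genotype behind each title. Nothing in the labels says how many animals went into a library.

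Per the submitters' processing notes, reads were processed with CASAVA, BWA and HOMER on the mm9 build. Versions, the control library of each peak call and its thresholds are not given in the sources used here. Each deposited list gives the chromosome, start, end and 1 value per peak, and the authors' value is a signal whose scale is not stated (called the score here). Within a list every distinct score was a whole multiple of 1 step (within a rounding tolerance of 0.05, steps from 0.155 to 0.40 searched): 0.172 for wild type STAT5A, 0.239 for wild type STAT5B and 0.210 for Stat5a-null STAT5B. This is the pattern that tag counts multiplied by 1 factor per library would give. Tags per peak were computed as the score divided by the step, and relative depth as the inverse ratio of steps, which holds only if the authors used 1 scale for all lists. Total reads per library are unknown. Apart from these, scores were used to rank and describe peaks within their own list. Heights of single peaks were not compared between lists.

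Starts were read as 0-based BED positions and are printed 1-based. The chromosome names and ends fit the mm9 chromosome lengths held in GenomeInfoDb 1.38.1. The gene table at hand is of another build (GRCm38), so no peak was assigned to a gene, and the planned gene groups, location of peaks relative to genes, and search for the STAT motif were not run. A few peaks lie on unplaced sequence: 20, 7 and 4 for wild type STAT5A, wild type STAT5B and Stat5a-null STAT5B. They were kept in overlaps and left out of random placements and densities.

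Peaks of different lists were called shared when they overlapped by at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent. As a reference, all peaks of a list were moved by 1 random distance per chromosome, around its end, in 100 placements on 20 chromosomes, and the range of overlap is given as a description. Sites are peaks of the 3 lists merged on overlap. Score quartiles and deciles were cut within a list. Clusters are runs of 5 or more peaks of a list with gaps of at most 12.5 kb, set beside 100 uniform placements. No test between conditions was made, since each group has 1 library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Overlap counts were tested on simulated data with 500 planted shared peaks, all found, and 18 counts from the real lists were the same with bedtools 2.31.1.

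Before the data were examined the design, the overlap rule, the alternatives and the rule for named peaks were fixed. Without an annotation of the build, that rule names the 10 highest-scoring peaks of each list, the 5 highest wild type STAT5B peaks without a Stat5a-null peak, the 5 highest Stat5a-null peaks without a wild type STAT5B peak, the 5 highest STAT5A peaks without STAT5B and the 3 clusters with the most STAT5A peaks. Examples from these are printed. Alternatives were an overlap of at least 50% of both peaks, peak centres within 100 bp, gaps of up to 500 bp, the higher-scoring 50% of each list, lists cut to the shortest, uniform placement, chromosomes 1 to 19 and X, deciles, and cluster gaps of 5 kb and 25 kb. Leaving out STAT5B peaks without STAT5A, and cutting or randomly thinning lists before clustering, were added after the data were seen.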

Results

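STAT5A and STAT5B are closely related transcription factors that prolactin signalling activates in the mammary epithelium. Their genomic binding was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mammary tissue collected on the day of parturition. Wild type mice carried both genes, and Stat5a-null mice retained Stat5b alone. Peak lists of 3 libraries were analysed: STAT5A in wild type tissue, STAT5B in wild type tissue and STAT5B in Stat5a-null tissue. Each group held 1 library, so no difference between groups has a replicate check and no p-value is given. Intervals are exact Clopper-Pearson 95% intervals and cover counting error over peaks only. The other 7 samples (STAT5A in Stat5a-null tissue, RNA polymerase II, H3K4me3 and input in either genotype) were not analysed here.

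The wild type STAT5A list held 26237 peaks, the wild type STAT5B list 6976 and the Stat5a-null STAT5B list 2578. All peaks of a list had 1 width, which was 276 bp for wild type STAT5A, 252 bp for wild type STAT5B and 258 bp for Stat5a-null STAT5B. Scores deposited by the authors ran from 11 to 261.6 with a median of 27.1 in the STAT5A list. They ran from 9.3 to 191.8 with a median of 17.7 in the wild type STAT5B list, and from 8.2 to 168.1 with a median of 16.7 in the Stat5a-null list. Every distinct score was a whole multiple of 1 step per list, within a rounding tolerance of 0.05. Read as the value of 1 tag, the step gave at least 64 tags per peak for STAT5A, with a median of 158. The weakest peak held 39 tags in each STAT5B list, and the medians were 74 tags in wild type and 79.5 tags in Stat5a-null tissue. If the authors scaled the 3 libraries alike, the STAT5A library was 1.39 times as deep as the wild type STAT5B library, and the Stat5a-null STAT5B library was 1.13 times as deep as the wild type one.

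The first comparison asked whether STAT5A and STAT5B occupied the same sites in wild type tissue. Nearly all STAT5B peaks overlapped a STAT5A peak, while most STAT5A peaks had no STAT5B peak. Whether either antibody also binds the other STAT5 protein was not tested here, so overlap of peaks need not mean binding by both. Of the 6976 wild type STAT5B peaks, 6888 overlapped a STAT5A peak by at least 1 bp, a share of 98.7% (95% interval 98.4% to 98.99%). The STAT5B list was 0.266 times as long as the STAT5A list, and each STAT5B peak could overlap only 1 STAT5A peak. The reverse share was 26.3% (25.7% to 26.8%), close to the highest that these lengths allow. This left 19349 STAT5A peaks without a STAT5B peak. In 100 random placements of the STAT5B peaks, by contrast, between 0.316% and 0.732% overlapped a STAT5A peak. The centres of overlapping STAT5A and STAT5B peaks lay a median of 19 bp apart (quartiles 9 bp and 33 bp), and 90.5% lay within 50 bp.

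STAT5A peaks with a STAT5B partner were mostly high-scoring ones. In the highest-scoring decile of the STAT5A list 99.2% (98.8% to 99.5%) had a wild type STAT5B peak. The share was 90.3% in the second decile, 54.3% in the third, 14.9% in the fourth and 3.13% in the fifth. It was 0 of 6559 in the lowest-scoring quartile. The highest STAT5A peaks included chromosome 1 from 140503457 to 140503732 (mm9, score 261.6), chromosome 7 from 126090920 to 126091195 (246.5) and chromosome 13 from 23563543 to 23563818 (239.3). All 3 of these sites also held a STAT5B peak in both genotypes, as did 9 of the 10 highest STAT5A peaks. The exception was chromosome 11 from 3045078 to 3045353, which ranked 3 in the list at a score of 239.9. It had no STAT5B peak in either genotype, and neither did a neighbouring peak on chromosome 11 from 3045844 to 3046119 with a score of 214.7. Both lie within 500 kb of the unsequenced first 3 Mb of the chromosome, at 45.1 kb and 45.8 kb from it. The next STAT5A peak without STAT5B ranked 1331, with a score of 108.6 (chromosome 11 from 5399968 to 5400243), and it had a wild type STAT5B peak within 500 bp.

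Only 88 wild type STAT5B peaks did not overlap a STAT5A peak (33 had none within 500 bp), yet several of them led the STAT5B list. Of the 10 highest wild type STAT5B peaks, 5 had no STAT5A peak. These were chromosome 11 from 108873125 to 108873376 (score 191.8, ranked first), chromosome 5 from 147072604 to 147072855 (153.5), chromosome 3 from 5860621 to 5860872 (134.4), chromosome 17 from 36368242 to 36368493 (105.1) and chromosome 16 from 57391507 to 57391758 (97.4). All 10 of the highest wild type STAT5B peaks, these 5 included, were also STAT5B peaks in Stat5a-null tissue. Whether the 5 peaks come from STAT5B alone, from antibody binding to another protein, or from repeated sequence or assembly gaps was not tested. With lists cut to their 2578 highest-scoring peaks, the overlap of STAT5A and wild type STAT5B was 86.3%, so the share of STAT5A sites with STAT5B depends on how far down each list peaks were called.

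The second comparison asked which STAT5B sites were found when STAT5A was missing. The Stat5a-null list was 0.370 times as long as the wild type STAT5B list and lay almost wholly within it. Of the wild type STAT5B peaks, 2426 overlapped a Stat5a-null STAT5B peak, or 34.8% (33.7% to 35.9%), and 4550 did not. With a list 0.370 times as long, this share could be little higher. Of the Stat5a-null peaks, 94.1% (93.1% to 94.98%) overlapped a wild type STAT5B peak. Random placements gave at most 0.115% and 0.389% for these shares. With both lists cut to 2578 peaks the overlap was 68.4% in each direction. The centres of shared peaks lay a median of 19 bp apart.

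High-scoring wild type STAT5B sites were mostly found in Stat5a-null tissue, and low-scoring ones mostly were not. The share with a Stat5a-null peak was 78.5% (76.5% to 80.4%) in the highest-scoring quartile of wild type STAT5B peaks, 39.4% in the second, 15.8% in the third and 5.39% (4.38% to 6.56%) in the lowest. By decile it fell from 90.8% to 3.30%. The intervals of the highest and lowest quartiles did not meet, so the trend with score exceeded the counting error. A shorter list that ranks sites alike would give such a fall whatever the genotype. Within wild type tissue, STAT5A peaks with STAT5B fell from 99.2% in the highest decile to 0 of 6559 in the lowest quartile. The trend alone therefore cannot be read as an effect of Stat5a loss, and it has no replicate check.

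**Figure D1:**
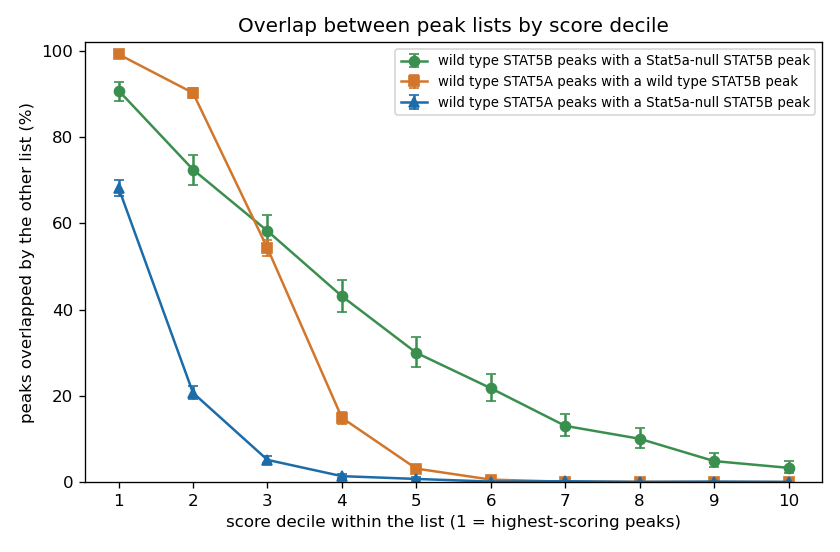
Share of peaks (y axis, percent) overlapped by another list, by score decile within the list (x axis, 1 = highest-scoring), with exact 95% binomial intervals as bars. Wild type STAT5B peaks with a Stat5a-null STAT5B peak (circles) fall from 90.8% to 3.30%, and wild type STAT5A peaks with a wild type STAT5B peak (squares) fall from 99.2% in the highest decile to 3.13% in the fifth, while STAT5A peaks with a Stat5a-null STAT5B peak (triangles) start at 68.3%.

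In the highest wild type decile, 64 of 698 STAT5B peaks had no Stat5a-null peak. The 2 highest of these were chromosome 19 from 61275535 to 61275786 (score 59.7, ranked 57) and chromosome 16 from 11144102 to 11144353 (58.0, ranked 67), and neither overlapped a STAT5A peak. The next 3 did overlap one, on chromosome 6 from 82522898 to 82523149 (48.2), chromosome 15 from 25879122 to 25879373 (48.0) and chromosome 13 from 72059898 to 72060149 (46.8). In the opposite direction, 152 Stat5a-null peaks had no overlapping wild type STAT5B peak. Their median score was 13, against 17.0 for the shared Stat5a-null peaks, and 84.9% of them ranked in the lower-scoring 50% of the Stat5a-null list. The highest, on chromosome 13 from 102944499 to 102944756 (score 32.4), had a wild type STAT5B peak within 500 bp. Of the 152 peaks, only 19 had one.

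The third comparison set STAT5B in Stat5a-null tissue against STAT5A in wild type tissue. Most STAT5B peaks found without STAT5A lay at STAT5A peaks of wild type tissue: 2537 of the 2578 Stat5a-null peaks, or 98.4% (97.8% to 98.9%), overlapped one. The very highest peaks differed. The share was 95.3% (92.0% to 97.6%) in the highest-scoring decile of Stat5a-null peaks, and only 4 of the 10 highest-scoring peaks overlapped a STAT5A peak. All 10 overlapped a wild type STAT5B peak. The Stat5a-null peaks covered 9.67% (9.31% to 10.0%) of STAT5A peaks, close to the highest share possible for a list 0.0983 times as long. Among STAT5A peaks, a Stat5a-null STAT5B peak was found at 36.9% (35.7% to 38.1%) of the highest-scoring quartile, 1.57% of the second, 0.122% of the third and 0.0762% of the lowest. In the highest-scoring decile (2624 peaks) the share was 68.3%. With lists cut to 2578 peaks it was 68.5%, which is nearly the same calculation and not a separate check.

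Merging overlapping peaks gave 26339 sites across the 3 lists. STAT5A alone was called at 19213 sites (72.9%). STAT5A and STAT5B were called in wild type tissue, without STAT5B in Stat5a-null tissue, at 4486 sites (17.0%). All 3 lists shared 2402 sites (9.12%). The remaining classes were small: 136 sites with wild type STAT5A and Stat5a-null STAT5B, 62 with wild type STAT5B alone, 26 with STAT5B in both genotypes and no STAT5A, and 14 with Stat5a-null STAT5B alone. When gaps of up to 500 bp were merged too, the last 3 numbers were 13, 20 and 6.

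**Figure D2:**
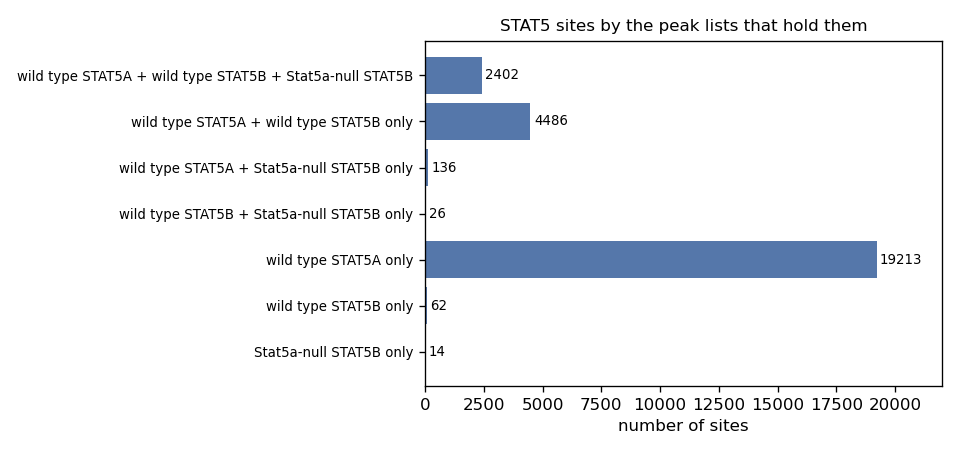
Number of merged sites (x axis) by the peak lists that hold a peak there (y axis), with the count beside each bar. Sites with STAT5A alone number 19213, sites in all 3 lists 2402, and sites that lack STAT5A fill the 3 classes of 26, 62 and 14 sites, which hold 20, 13 and 6 when gaps of up to 500 bp are merged.

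Clusters of sites were frequent for STAT5A. With neighbouring peaks joined across the gap stated with the processing, the STAT5A list held 434 clusters of 5 or more peaks, with 9.95% of its peaks. The number depends on the gap, with 34 clusters at 5 kb and 1049 at 25 kb. Uniform random placement gave between 1 and 13 clusters. The wild type STAT5B list held 21 clusters (0 to 1 at random) and the Stat5a-null list none, its largest group having 4 peaks. At 25 kb these numbers were 64 and 4, and at 5 kb 4 and none. Cluster numbers fell with list length: thinned at random to 2578 peaks, the STAT5A list held 0 to 1 clusters over 100 draws and the wild type STAT5B list 0 to 2, and their 2578 highest-scoring peaks held 2 and 1. Of the 434 STAT5A clusters, 354 (81.6%, 77.6% to 85.1%) contained a wild type STAT5B peak and 217 (50%, 45.2% to 54.8%) a Stat5a-null STAT5B peak. Among all STAT5A peaks 26.3% and 9.67% had these partners, and 5 or more peaks per cluster raise the share by themselves. No reference for clusters was computed, so these shares do not show a preference of STAT5B for clusters.

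The 3 largest STAT5A clusters differed in how many STAT5B peaks they held. The cluster on chromosome 11 from 117819490 to 117877051 (57.6 kb) held 16 STAT5A peaks, 9 wild type STAT5B peaks and 2 Stat5a-null STAT5B peaks. The cluster on chromosome 15 from 66911887 to 66993369 (81.5 kb) also held 16 STAT5A peaks, with 13 wild type STAT5B peaks, 12 of them on a STAT5A peak, and 5 Stat5a-null STAT5B peaks. The cluster on chromosome 13 from 103636594 to 103696332 (59.7 kb) held 13 STAT5A peaks and 6 wild type STAT5B peaks, and no Stat5a-null peak was called there.

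**Figure D3:**
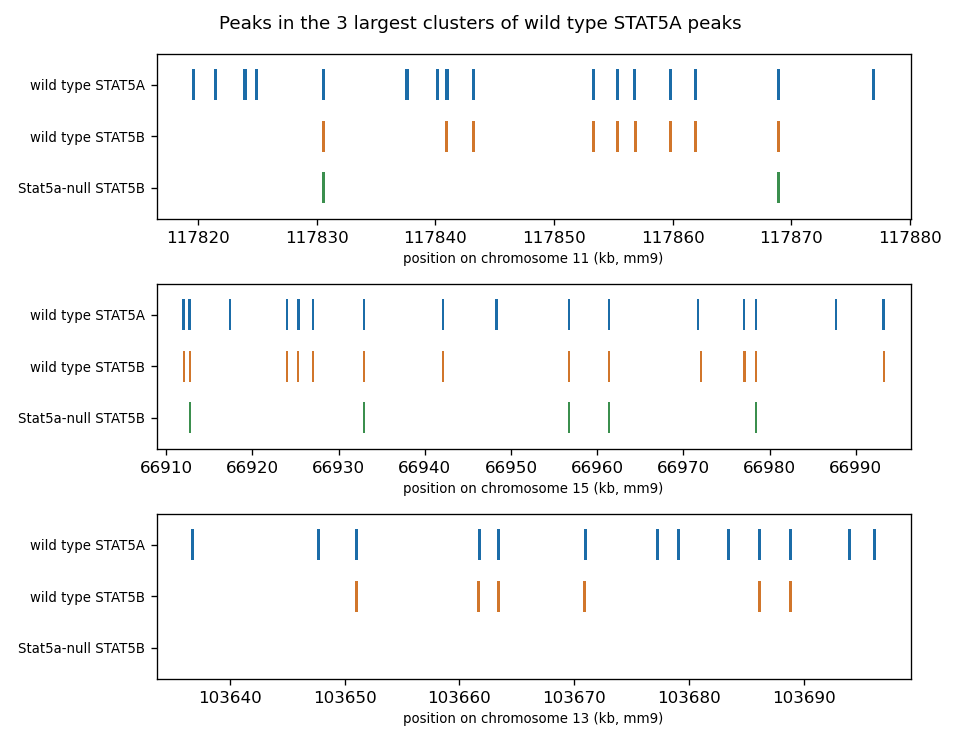
Peak positions (x axis, kb, mm9, drawn to scale) in the 3 largest clusters of wild type STAT5A peaks, with 1 row per peak list. On chromosome 11 the rows hold 16, 9 and 2 peaks for wild type STAT5A, wild type STAT5B and Stat5a-null STAT5B, on chromosome 15 they hold 16, 13 and 5, and on chromosome 13 they hold 13 and 6 with none in the Stat5a-null row.

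Sites were spread over the autosomes and sparse on the X chromosome. STAT5A peaks had a median density of 10.0 per Mb over the autosomes, from 7.92 on chromosome 14 to 14.0 on chromosome 11, and 3.22 per Mb on the X. The X chromosome makes up 6.31% of the placed sequence. It held 2.05% (1.88% to 2.23%) of STAT5A peaks, 1.15% (0.911% to 1.43%) of wild type STAT5B peaks and 0.738% (0.445% to 1.15%) of Stat5a-null STAT5B peaks. Chromosome 19 had the highest STAT5B density in both genotypes, at 4.04 peaks per Mb in wild type and 1.70 in Stat5a-null tissue.

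**Figure D4:**
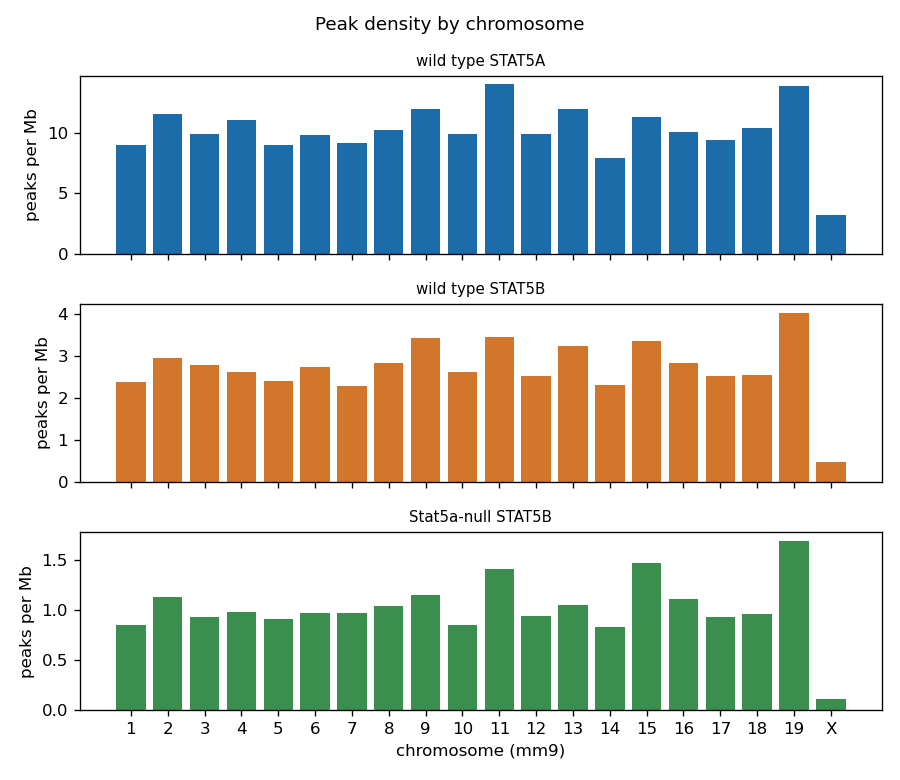
Peaks per Mb (y axis, starting at 0, with its own scale in each panel) on each mm9 chromosome (x axis) for the 3 peak lists. The X chromosome is the lowest bar in every panel, at 3.22 peaks per Mb for wild type STAT5A, 0.480 for wild type STAT5B and 0.114 for Stat5a-null STAT5B.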

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

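Across 78 alternatives of 27 values, 43 stayed within the counting interval, within the range of placements or within 1.5 times the count, and 35 moved. Cutting lists to the shortest length moved the overlap of STAT5A and wild type STAT5B to 86.31%, of wild type and Stat5a-null STAT5B to 68.39%, and of STAT5A and Stat5a-null STAT5B to 68.54%, in each direction by construction. Requiring 50% of both peaks or centres within 100 bp put the share of wild type STAT5B peaks with STAT5A at 98.29% and 97.96%, and allowing a 500 bp gap at 99.53%. Centres within 100 bp gave 92.59% of Stat5a-null peaks with wild type STAT5B and 97.25% with STAT5A. The 500 bp gap gave 98.99% of Stat5a-null peaks with STAT5A. With the higher-scoring 50% of each list, 95.03% of Stat5a-null peaks had wild type STAT5B. That setting, which removes 50% of peaks by construction, gave 13173 sites: 1209 in all lists, 2231 with STAT5A and STAT5B in wild type alone, 57 with STAT5A and Stat5a-null STAT5B, 16 with STAT5B in both genotypes, 9621 with STAT5A alone, 32 with wild type STAT5B alone and 7 with Stat5a-null STAT5B alone. Merging across 500 bp gaps left 13 sites with wild type STAT5B alone and 6 with Stat5a-null STAT5B alone. Deciles in place of quartiles gave 90.83% and 3.30% for the highest and lowest wild type STAT5B peaks with a Stat5a-null peak, and 68.25% for the highest STAT5A peaks. Cluster numbers moved most: gaps of 5 kb gave 34 (STAT5A) and 4 (wild type STAT5B), gaps of 25 kb gave 1049, 64 and 4 (Stat5a-null), and lists cut to 2578 peaks, added after the data were seen, gave 2 and 1, or a median of 0 for both when thinned at random. Leaving out STAT5B peaks without STAT5A within 500 bp, also added later, gave 34.65% and 94.28% for the overlap of the STAT5B lists. With 1 library per group no replicate could be left out, and total reads, which set how many weak sites can be called, are unknown.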

Other observations

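The tests on relative depth, on peaks found in Stat5a-null tissue alone and on the X chromosome were chosen after the values they measure had been seen in part, and the other tests were set before. A group of STAT5B sites without STAT5A stood apart in position. Of the 33 wild type STAT5B peaks with no STAT5A peak within 500 bp, 9 (27.3%, exact 95% interval 13.3% to 45.5%) lay in 2.02 Mb of chromosome 13 from 21826732 to 23848905 (mm9), and 8 of these 9 were found in Stat5a-null tissue too. Of the 6943 other wild type STAT5B peaks, 5 (0.0720%, 0.0234% to 0.168%) lay in the same region, and 4 of these 5 were found in Stat5a-null tissue as well. The region was singled out after its peaks were seen, and its ends are those of the outermost of the 9 peaks. The shares and intervals are therefore no test of enrichment. No gene was assigned there because an mm9 annotation was not used here.

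The X chromosome was sparse in STAT5A sites, and more so among the strongest. The hypothesis that its share is the same at weak and strong sites was tested on the 2576 placed peaks among the highest-scoring STAT5A peaks, as many as the Stat5a-null list holds. The X share was 0.543% there (0.297% to 0.910%) and 2.21% (2.03% to 2.41%) among the 23641 others, which argues against an equal share. Nearly all of these strongest peaks also have STAT5B, and the low X share of the STAT5B lists had been seen before. Among STAT5A peaks with no STAT5B peak in either genotype, where the comparison was added later, the X held 2.24% (1.95% to 2.56%) of the 9600 higher-scoring and 2.49% (2.19% to 2.82%) of the 9600 lower-scoring peaks, so with overlapping intervals no trend with score was shown there. A further hypothesis, that wild type STAT5B peaks in STAT5A clusters are more often found in Stat5a-null tissue, was not borne out. The raw shares were 39.7% of 889 clustered and 32.5% of 2284 single peaks. After standardising over score deciles the difference was -1.05 percentage points (bootstrap 95% interval -4.02 to 1.996). The rest of the 6976 wild type STAT5B peaks, counted neither as clustered nor as single, were left out.

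The first pattern weighed is the shorter STAT5B list of Stat5a-null tissue. A lower depth of that library is argued against by the value of 1 tag, which puts it at 1.135 times the depth of the wild type STAT5B library if the authors used 1 scale. An even fall of signal against a fixed calling threshold may explain why weak sites dropped out, but its test was void: highest-decile STAT5B peaks found in Stat5a-null tissue had a STAT5A score percentile 0.358 (bootstrap 95% interval 0.170 to 0.726) above those not found, the direction it predicts, but the interquartile range of 1.52 percentiles was too narrow for the 5 set in advance. The difference was 0.0648 (-0.309 to 0.728), 1.26, 1.03 and 2.39 (1.70 to 2.95) in deciles 2 to 5, which were added after the data were seen, so this explanation stays open. A lower yield of the immunoprecipitation stays open: STAT5B peaks without STAT5A nearby were found in Stat5a-null tissue at 60.6% (42.1% to 77.1%), and rank-matched other peaks at 57.6%. The lower STAT5 dose that the genotype gives stays open too, untested, since genotype and library are the same split of the data. The same holds for any other difference between the tissues, such as their mix of cells. Binding of the STAT5B antibody to STAT5A in wild type tissue was not tested either.

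The second pattern is the set of high-scoring STAT5B peaks without STAT5A, 17 of which fell in the highest decile with no STAT5A peak within 500 bp, 15 of them found in both genotypes. Being found in both does not set them apart, since 634 of all 698 highest-decile STAT5B peaks (90.8%) were. Small shifts in peak position are argued against, since only 10.5% (1.30% to 33.1%) of the 19 highest-decile peaks without an overlap had a STAT5A peak within 500 bp. A position within 500 kb of a chromosome's sequenced ends or on unplaced sequence is argued against as the main source, at 17.6% (3.799% to 43.4%) of these 17 peaks, though this exceeds the 0.441% (0.0909% to 1.28%) of other highest-decile peaks, so it may account for some. Binding by the STAT5B antibody to another protein, binding by STAT5B alone, internal assembly gaps and repeated sequence were not tested.

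The third pattern is the 152 Stat5a-null STAT5B peaks without a wild type STAT5B peak. Sites near the calling threshold that were missed in the wild type STAT5B list are a candidate explanation that stays open: 90.8% (85.0% to 94.9%) lay on a wild type STAT5A peak, but only 41 Stat5a-null peaks in all lacked one, so the share was at least 73.0% in any case and decides nothing. After allowing gaps of 500 bp to either wild type list, 6 Stat5a-null peaks had no wild type partner, the highest on chromosome 7 from 151859314 to 151859571 with a score of 17.7. No biological explanation for these 6 was tested.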
